A study of Mus musculus with 4 samples.

How the data were processed

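Primary mouse oligodendrocyte precursor cells were differentiated for 1 day with T3, the thyroid hormone used to start oligodendrocyte differentiation in culture, and total RNA was taken with Trizol and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. There were 4 samples. The 2 control samples carry a genotype label that names both lncOL1+/+ and lncOL1+/- without saying which sample is which, and the 2 knockout samples are labelled lncOL1-/-. All 4 are of a mixed strain background. Nothing in the labels says that the samples came from separate animals or cultures, so p-values then measure only the spread between these samples, which may be technical.

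The submitters' processing notes name CASAVA, TopHat, Cufflinks and Cuffdiff and the mouse genome build mm10, with no versions, options or roles. The annotation and the strand setting of the counting are not given in the sources used here. Each sample has 1 table of gene-level FPKM (fragments per kilobase of transcript, scaled to the mapped fragments), computed by the authors and deposited per sample, with a status for each row per the file headers. A further deposited table holds the authors' Cuffdiff comparison of the groups, with 1 pooled FPKM for each group, a log2 fold change, a test statistic, a p-value and a q-value per gene, per the file headers. Its values are quoted as the authors' and were not combined with the values computed here.

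FPKM are not counts, so no count model was used. The number of reads behind each value is not given in the files. Summed FPKM was 383128 and 373484 in control replicates 1 and 2 and 381104 and 375762 in knockout replicates 1 and 2. Among 562 rows with all 4 values above 0 and under 0.1 FPKM, the commonest ratio between libraries gave relative depths of 1.18, 0.95 and 1.16 for control replicate 2, knockout replicate 1 and knockout replicate 2 against control replicate 1. These are estimates of relative depth only.

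Each sample table had 23931 rows under 23444 gene symbols. Rows of the same symbol were summed, which concerned 258 symbols, and 9 symbols with a status other than OK in any sample were left out. The 11361 genes with a mean of at least 1 FPKM over the 4 samples were tested. log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an expression trend), with no covariate, for knockout minus control, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene with an adjusted p under 0.05 is called higher or lower. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The fit left 2 residual degrees of freedom, with 4.6 prior degrees of freedom from the other genes. On simulated data over 11360 genes, it recovered 47.8%, 83.6% and 92.4% of the genes changed by 0.5, 1 and 2 on the log2 scale. In that simulation 4 of 153 calls were false. Its noise was independent between genes and drawn from the spread within these groups, for genes already past the filter. It cannot show false calls from differences shared by genes, such as those between cultures, or the effect of the filter.

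The 27 gene lists, the rule for the named genes and the alternatives at the end, except where said, were fixed before the data were examined. The lists cover oligodendrocyte stages, other cell types, Polycomb repressive complex 2 (PRC2), signalling, stress and housekeeping genes. The 22 lists with at least 5 tested genes were compared with the other genes by limma's camera with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists, and again with an estimated correlation and with fry, a test of whether a list's genes move on balance one way, whose mixed form tests for changes in either direction. With an estimated correlation, camera refers its statistic to the 2 residual degrees of freedom, so few lists could pass. A list that does not pass this form is therefore not shown to be unchanged. For each list, calls were counted over all genes tested and adjusted over the list alone. A list member was matched by its symbol or by a synonym in the RefSeq gene table, which was needed for Epb41l2, Zfp24 and Msmo1, listed in the files as Epb4.1l2, Zfp191 and Sc4mol.

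The rule for the named genes takes lncOL1, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap (predicted genes without a conventional symbol left out), up to 4 members with the highest mean FPKM and up to 2 with the smallest p in each list described, all PRC2 subunits, and the nearest protein-coding genes to lncOL1. Members were named for the lists past the preset-correlation test and for the lineage transcription factor, precursor and PRC2 lists. Genes named outside the rule are marked where they appear, and some genes that the rule takes are not reported here.

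lncOL1 was identified as 9630013A20Rik, the only symbol with the synonym lncOL1 in the RefSeq gene table of the assembly that mm10 corresponds to, and gene structures came from GENCODE M21 on the same assembly. In the authors' table only genes with status OK were used. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, and tables were read with pandas 2.3.3. The alternatives were smaller pseudocounts, other filters on low values, rescaling by the median of ratios, to TPM and by quantiles, limma without the trend and with robust moderation, a replicate block, leaving out each library in turn, leaving out symbols with more than 1 row, other thresholds on the authors' table and a wider window around the locus.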

Results

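RNA of primary mouse oligodendrocytes, in 2 control and 2 lncOL1 knockout samples, was sequenced after 1 day of differentiation, to find the genes whose expression differs on loss of the long noncoding RNA lncOL1. Between 11284 and 11357 genes reached 1 FPKM in each library. Across the 11361 genes tested, log2(FPKM + 1) correlated at r = 0.9845 within both groups and at 0.9818 to 0.9841 between libraries of different groups. These correlations are across genes, which are not independent replicates. The files give no read counts, so the precision of a value rests on the spread between the 2 libraries of a group.

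lncOL1 itself was strongly lower in the knockout. Its FPKM was 28.9 and 34.0 in the control libraries and 5.54 and 5.06 in the knockout libraries, a log2 fold change of -2.36 (SE 0.097, limma adjusted p = 0.000389), and the call held under every alternative run, each library left out included (adjusted p up to 0.0229). The authors' deposited table gives 32.7 FPKM in control and 5.74 in knockout for it, with a log2 fold change of -2.51. The gene (9630013A20Rik) spans positions 84458838 to 84476424 of chromosome 14 in the files (mm10) and is annotated as an antisense transcript on the minus strand. It lies wholly within intron 1 of Pcdh17, a protocadherin gene on the plus strand that spans 84443563 to 84539002 in GENCODE, and 0 of its exons overlap a Pcdh17 exon. Since the strand setting of the counting is not given, reads of this antisense pair from unspliced RNA cannot be told apart. Which part of the locus was removed is not given in the sources used here.

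**Figure D1:**
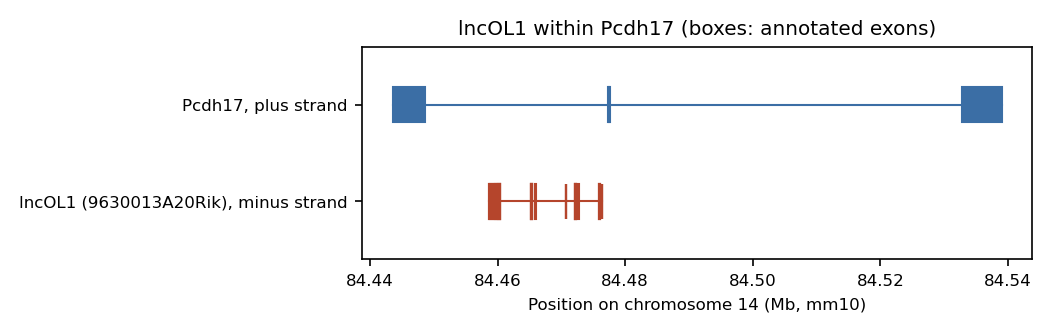
Map of lncOL1 (9630013A20Rik) and Pcdh17 on chromosome 14, with position in Mb (mm10) on the horizontal axis and annotated exons as boxes. lncOL1, at 84458639 to 84476424 in the annotation, lies in intron 1 of Pcdh17, from 84448654 to 84477322.

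The neighbouring gene did not differ detectably. Pcdh17 had 24.8 ± 1.12 FPKM in control and 25.02 ± 0.627 in knockout (SD, n = 2 each, log2 fold change 0.01, SE 0.071, limma adjusted p = 0.968). It was the 1 other gene tested within 1 Mb of lncOL1, and 0 of the 8 genes tested within 5 Mb were called by limma. The authors' deposited table gives q = 0.990 for Pcdh17. On chromosome 14 as a whole, 5 of 390 tested genes were called (1.28%, lncOL1 left out), against 1.3% on the other chromosomes (two-sided Fisher's exact p = 1). The mixed strain background means that strain differences around the locus cannot be separated from effects in cis.

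Across the transcriptome, 60 genes were higher and 89 were lower in the knockout among 11361 tested (limma, adjusted p under 0.05), and 810 and 748 had an unadjusted p under 0.05. Among called, conventionally named genes, large falls with expression in both groups, after lncOL1, were in the small nucleolar RNA Snora65, in Lrrc16a, which encodes a capping protein regulator of actin, and in Tmem2 and Lpar1. Lpar1, a lysophosphatidic acid receptor, went from 20.9 ± 1.27 to 8.78 ± 1.02 FPKM (SD, n = 2 each, log2 fold change -1.17, limma adjusted p = 0.00495). Ddc, which encodes aromatic amino acid decarboxylase, went from 66.5 ± 1.11 to 29.8 ± 0.530 FPKM (log2 fold change -1.13, limma adjusted p = 0.00307), and Rgs16, a regulator of G protein signalling, fell by 1.08 on the log2 scale. Calls were lost without knockout replicate 2 for Lrrc16a (adjusted p = 0.0557), Lpar1 and Rgs16 (adjusted p = 0.0774 for both) and Snora65 (adjusted p = 0.296), without knockout replicate 1 for Rgs16 and Snora65 (adjusted p = 0.0550 and 0.206), and without control replicate 2 for Lpar1 (adjusted p = 0.0534). The values of Snora65 were 39.7 and 23.4 FPKM in control and 9.89 and 8.69 in knockout. The authors' deposited table gives q = 0.963 for it.

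Among called, conventionally named genes with expression in both groups, the largest rises were in Dll3, a Notch ligand, the tubulin gene Tuba1c and the imprinted noncoding RNA H19. Dll3 (chromosome 7, 28293555 to 28301785) rose from 8.57 ± 0.419 to 23.04 ± 4.92 FPKM (SD, n = 2 each, log2 fold change 1.31, SE 0.136, limma adjusted p = 0.0105). H19 (chromosome 7, 142575532 to 142578146) rose from 243.7 ± 25.3 to 569.5 ± 8.59 FPKM (log2 fold change 1.23, SE 0.088, limma adjusted p = 0.00433). Without control replicate 1, control replicate 2 and knockout replicate 2 the adjusted p of Dll3 was 0.112, 0.0888 and 0.0700, and without knockout replicates 1 and 2 that of H19 was 0.0726 and 0.0910. Tuba1c rose by 1.24 on the log2 scale here, but the authors' deposited table gives 0.17 with q = 0.101, and its reads can be shared with near-identical tubulin genes, which was not tested, so its change is uncertain. Fcrls, Laptm5 and Tyrobp, all known from microglia, rose by 1.14, 1.03 and 1.01. Slc7a11, the cystine transporter, rose by 0.96, Slc13a3, a dicarboxylate transporter, by 1.05, and Ppp1r3e, a regulatory subunit of a phosphatase, by 1.12. Without knockout replicates 1 and 2 the adjusted p was 0.0836 and 0.111 for Fcrls, 0.0726 and 0.0866 for Slc13a3, 0.0859 and 0.101 for Slc7a11 and 0.211 and 0.217 for Ppp1r3e. The call was also lost without control replicate 1 for Slc7a11 (adjusted p = 0.0605), without control replicate 2 for Ppp1r3e (adjusted p = 0.0986) and without knockout replicate 2 for Tuba1c (adjusted p = 0.0700).

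4 further genes of the naming rule had values at or near 0 in every library of 1 group, and no fold is given for them. Mir374 was listed at 19.6 and 15.7 FPKM in control and 0 in both knockout libraries, and Mir1188 at 0 in both control libraries and 8.84 and 7.67 in knockout. Ndufs5 was listed at 4.67 and 8.39 in control and 0.00540 and 0.00401 in knockout, and the processed pseudogene Atp6v0c-ps2 at 8.999 and 5.34 in control and 0.00377 and 0.00411 in knockout. In the authors' deposited table the q was 0.776 for both microRNAs and 0.804 for Ndufs5, and Atp6v0c-ps2 had a log2 fold change of -0.67 with q = 1.07e-11.

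The number of calls changed strongly with the filter and with each library left out. Leaving out a library leaves 1 sample in its group and fewer residual degrees of freedom, and calls fell whichever library it was. A call lost in this way thus does not show that a change rests on 1 library. Mbp, for example, was at 2683 and 2655 FPKM in the control and 1501 and 1520 in the knockout libraries. With no filter on low values, 1 gene was higher and 3 were lower among 17397 tested, and the counts of higher and lower genes were 16 and 23 without control replicate 1, 16 and 26 without control replicate 2, 16 and 7 without knockout replicate 1, and 11 and 5 without knockout replicate 2. Of the 46 called genes named in the text that have a fold change, lncOL1 and Ddc kept their call with each library left out and 26 lost it with every library left out, Mbp among them. The call was kept by 16 without control replicate 1, 16 without control replicate 2, 8 without knockout replicate 1 and 2 without knockout replicate 2.

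**Figure D2:**
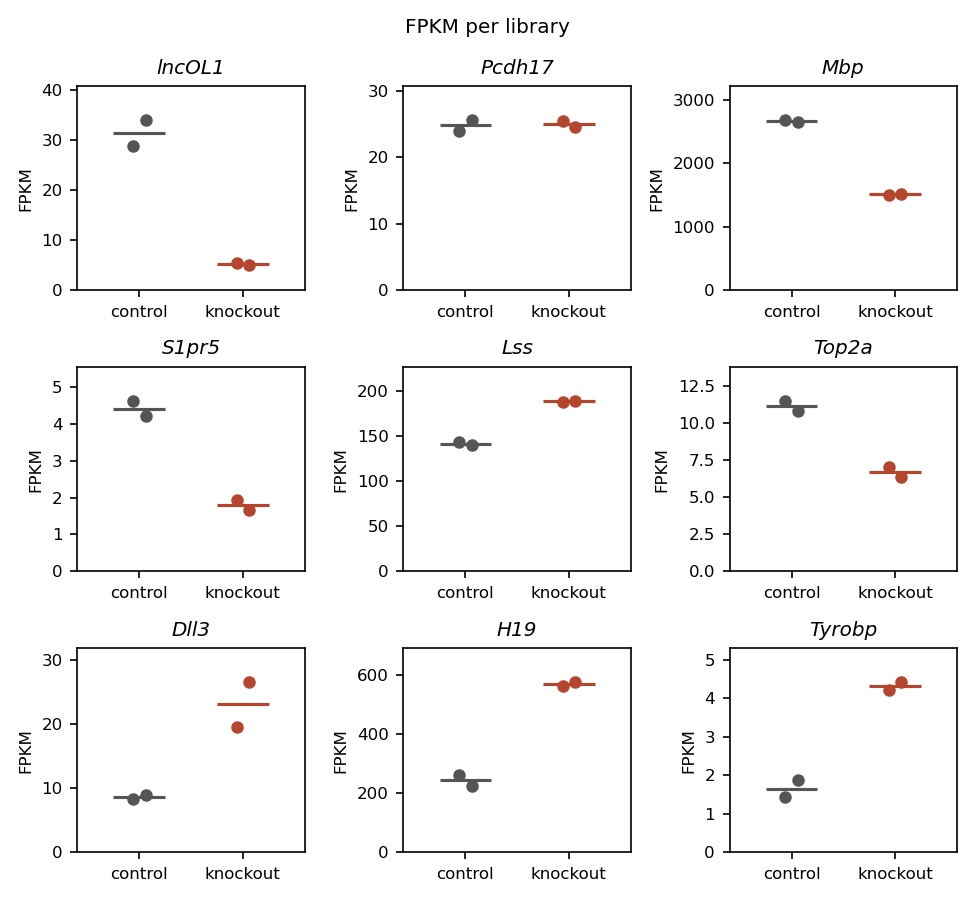
FPKM of 9 genes in each library, with 2 control (grey) and 2 knockout (red) points per panel and a line at the group mean. Control and knockout points do not overlap for lncOL1, Mbp, S1pr5, Lss, Top2a, Dll3, H19 and Tyrobp, and they overlap for Pcdh17.

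The myelin list was lower in the knockout by camera at preset correlation, but not with an estimated correlation (adjusted p = 0.291). Of 35 tested members of the myelin and maturing oligodendrocyte list, 5 fell, 0 rose and 30 did not pass (limma), and 11 were lower and 2 higher adjusted over the list alone. The adjusted p at preset correlation was 2.49e-05. Mbp, which encodes myelin basic protein (chromosome 18, 82475123 to 82585637), fell from 2669 ± 19.7 to 1511 ± 13.9 FPKM (SD, n = 2 each, log2 fold change -0.82, SE 0.068, limma adjusted p = 0.00504). Its adjusted p was 0.0653 and 0.0608 without control replicates 1 and 2, and 0.104 and 0.139 without knockout replicates 1 and 2. Called members also included S1pr5, a sphingosine phosphate receptor, Adamts4, a metalloproteinase, and Gpr37, named after their values were seen, with log2 fold changes of -0.95, -0.67 and -0.50. With each library left out in turn their calls were lost (adjusted p 0.0608 to 0.220). The abundant members Cnp and Sirt2 did not pass, with log2 fold changes of -0.16 and -0.12 (limma adjusted p = 0.361 and 0.516), although Sirt2 was at 0 after quantile normalization.

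Genes of newly formed oligodendrocytes moved in both directions. Of 21 tested members of that list, which includes lncOL1, 4 fell and 2 rose (limma), and 8 were lower and 3 higher adjusted over the list alone. Without lncOL1, an alternative chosen after the data were seen, 3 of 20 fell and 2 rose, with a camera adjusted p = 0.0403 at preset correlation, an adjusted p = 0.335 with an estimated correlation and a fry adjusted p = 0.0770. With lncOL1 these were adjusted p = 0.00532, adjusted p = 0.291 and adjusted p = 0.0478. Tmem2, a hyaluronidase of the cell surface, fell from 15.4 ± 1.04 to 5.85 ± 0.218 FPKM (SD, n = 2 each, log2 fold change -1.26, limma adjusted p = 0.00352), a call lost without knockout replicate 2 (adjusted p = 0.0698). Named after their values were seen, Rras2 and Tmem163 fell by 0.73 and 0.42 on the log2 scale, while the sialidase gene Neu4 rose by 0.64 and Lims2 by 0.57. These 4 calls were lost with each library left out (adjusted p 0.0763 to 0.261), and the authors' deposited table gives q = 0.847 for Lims2. The most abundant members did not pass, with log2 fold changes of 0.06 for Bcas1, 0.06 for Fyn, 0.15 for Gpr17 and -0.38 for Nfasc (limma adjusted p = 0.877, 0.836, 0.404 and 0.0561), and Fyn was at -0.02 after quantile normalization.

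No member of the lineage transcription factor list was called, a list that also holds chromatin regulators and a growth factor gene. Of 23 tested, 0 were called over all genes, 3 higher and 5 lower had an unadjusted p under 0.05, and 2 higher and 2 lower passed adjusted over the list alone. The authors' deposited table calls 2 of them higher and 5 lower. The camera adjusted p was 0.758 at preset correlation and the adjusted p was 0.852 with an estimated correlation, while fry's mixed test for changes in either direction gave an adjusted p = 0.0266, and the list's mean of -0.02 and median of 0.001 differed in sign. Olig1 had a log2 fold change of 0.08, Olig2 of 0.20, Sox10 of 0.02 (-0.02 after quantile normalization), Sox8 of 0.31, Nkx2-2 of 0.46 and Myrf, the activator of myelin genes, of -0.11, none past the limma test. Among 27 tested genes of oligodendrocyte precursors 0 were called, 7 higher and 0 lower had an unadjusted p under 0.05, and 0 passed adjusted over the list alone. The authors' deposited table calls 2 higher and 1 lower. Their camera adjusted p was 0.0712 at preset correlation (adjusted p = 0.0145 without knockout replicate 1) and the adjusted p was 0.573 with an estimated correlation. Log2 fold changes were 0.07 for Tnr, 0.07 for Scrg1, 0.39 for Pcdh15 and 0.37 for Traf4 (limma adjusted p = 0.762, 0.809, 0.0932 and 0.123).

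The cholesterol list was higher and the cell cycle list lower by camera at preset correlation, and neither with an estimated correlation (adjusted p = 0.225 for both). The estimated correlation of the cholesterol list was -0.006, below the preset 0.01, yet its unadjusted camera p went from 4.19e-16 to 0.0121. That loss is thus not due to correlation between its genes, and the form with 2 residual degrees of freedom cannot decide here. All 23 tested cholesterol genes had a positive log2 fold change in the fit of all 4 samples, with a median of 0.28. Of these 2 rose over all genes tested (limma) and 18 rose adjusted over the list alone, with a camera adjusted p = 9.21e-15 at preset correlation and an adjusted p = 0.225 with an estimated correlation. Lss, lanosterol synthase, rose from 141.4 ± 2.53 to 188.0 ± 0.471 FPKM (SD, n = 2 each, log2 fold change 0.41, limma adjusted p = 0.0456). With each library left out in turn its adjusted p was 0.211 to 0.289. Fdps had a log2 fold change of 0.39, Sc4mol (Msmo1) of 0.28 and Hmgcs1 of 0.14, none past the limma test. The authors' deposited table calls 15 of the 23 higher and 0 lower. Its q was 1.15e-05 for Fdps, 0.00569 for Sc4mol and 0.469 for Hmgcs1. Of 37 tested cell cycle genes 2 fell and 0 rose (limma), and 17 fell adjusted over the list alone, with a camera adjusted p = 6.95e-13 at preset correlation and an adjusted p = 0.225 with an estimated correlation. Top2a, topoisomerase II alpha, fell from 11.2 ± 0.467 to 6.72 ± 0.481 FPKM (log2 fold change -0.66, limma adjusted p = 0.0174), and the mitotic kinesin gene Kif11 from 3.96 ± 0.0952 to 2.46 ± 0.149 (log2 fold change -0.52, limma adjusted p = 0.0484). With each library left out in turn the adjusted p was 0.110 to 0.197 for Top2a and 0.198 to 0.296 for Kif11. Pcna, Rrm1, Mcm7 and Ube2c had log2 fold changes of -0.27, -0.27, -0.16 and -0.10, none past the limma test.

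The series title links lncOL1 with Suz12, a subunit of PRC2, the complex that methylates histone H3 at lysine 27. None of the 10 tested genes of PRC2 subunits and cofactors was called by limma, 0 had an unadjusted p under 0.05, and 0 were called in the authors' deposited table. The camera adjusted p was 0.758 at preset correlation and the adjusted p was 0.853 with an estimated correlation. These RNA levels do not bear on whether lncOL1 acts with the Suz12 protein or on histone methylation, which were not measured. Suz12 had 10.3 ± 1.09 FPKM in control and 10.8 ± 0.559 in knockout (SD, n = 2 each, log2 fold change 0.06, SE 0.091, limma adjusted p = 0.857). The log2 fold changes of Ezh2, Eed, Ezh1 and Jarid2 were -0.15, -0.04, 0.07 and -0.05, and those of Aebp2, Mtf2, Phf1, Rbbp4 and Rbbp7 were -0.10, 0.04, 0.04, -0.01 (0.001 after quantile normalization) and -0.01. Of 66 classical PRC2 target genes of development, 9 reached the filter and 0 were called by limma, with 1 higher and 2 lower at an unadjusted p under 0.05 and 0 called in the authors' deposited table. The filter removes silent genes, so release of repressed genes was hardly tested. Of 23 members above 0 and below the filter, 12 were higher in the knockout, against 56.1% of all such genes. Picked after their values were seen, Six3 went from 0.452 to 1.089 FPKM and Nkx2-1 from 0.279 to 0.758. The list's camera adjusted p was 0.304 at preset correlation and the adjusted p was 0.573 with an estimated correlation. Its direction turned from lower to higher under TPM scaling. The minimum of 1 was applied after that scaling, so genes of lower FPKM entered (12591 tested), Six3 and Nkx2-1 among them. The turn thus came with a changed set of members and is not an effect of scaling alone. Meis2, Lhx2, Meis1 and Wnt5a had log2 fold changes of -0.09, -0.19, -0.21 and 0.29.

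**Figure D3:**
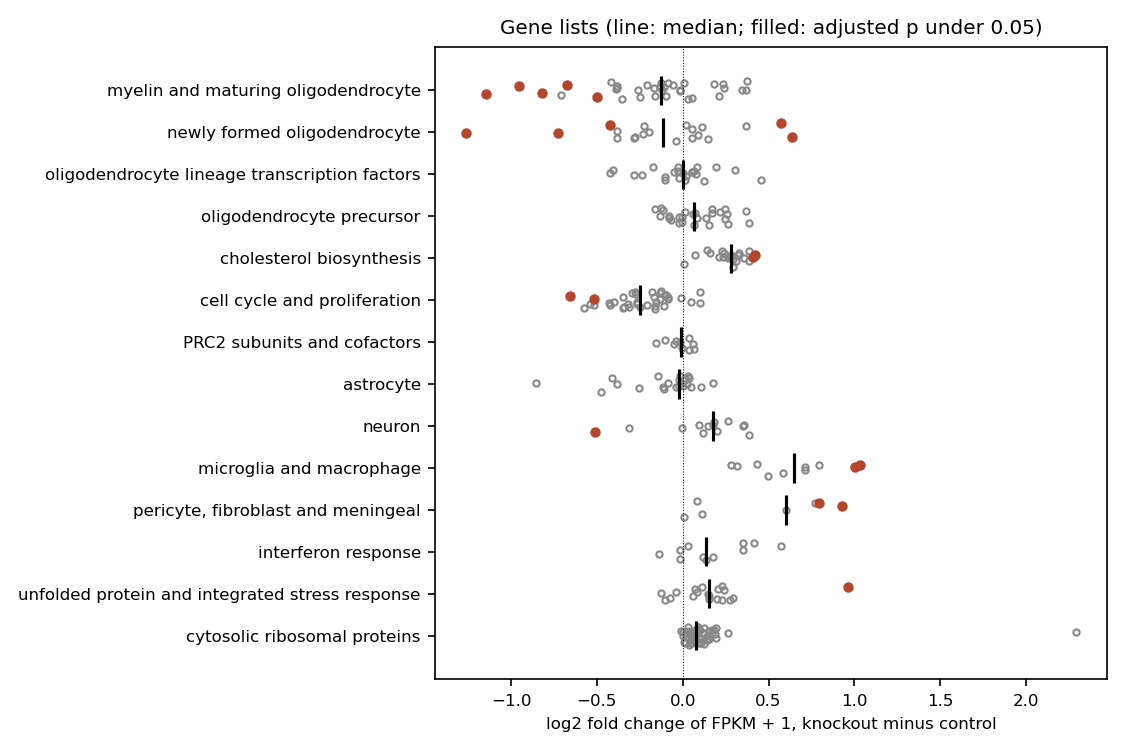
Log2 fold change of FPKM + 1 (knockout minus control) of the tested members of 14 gene lists, 1 point per gene, with filled points for an adjusted p under 0.05 and a line at the median. lncOL1 itself is left out, and the far point among ribosomal genes is Rps27, at 2.29, which did not pass the test.

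Markers of other cell types were compared next. Of 10 tested microglia and macrophage genes 2 rose over all genes tested (limma) and 9 rose adjusted over the list alone, with a camera adjusted p = 4.12e-10 at preset correlation and an adjusted p = 0.231 with an estimated correlation. Tyrobp was at 1.66 ± 0.316 FPKM in control and 4.32 ± 0.149 in knockout and Laptm5 at 1.54 ± 0.0583 and 4.21 ± 0.567 (SD, n = 2 each). Laptm5 lost its call with each library left out (adjusted p 0.0642 to 0.111) and Tyrobp without control replicate 1 (adjusted p = 0.0683) and knockout replicates 1 and 2 (adjusted p = 0.125 and 0.167). Lyz2, an abundant member, had a log2 fold change of 0.28 and did not pass. Of 7 tested genes of pericytes, fibroblasts and meninges 2 rose (limma) and 4 rose adjusted over the list alone, with a camera adjusted p = 7.43e-05 at preset correlation and an adjusted p = 0.260 with an estimated correlation, a result lost with no filter on low values (adjusted p = 0.701). The 2 members called over all genes, Tagln and Acta2, are genes of the contractile cytoskeleton. The 4 that rose adjusted over the list alone also include a gene outside it, not named here. Tagln went from 7.19 ± 0.219 to 14.6 ± 0.0252 FPKM (SD, n = 2 each, log2 fold change 0.93, limma adjusted p = 0.00433) and Acta2 rose by 0.80, while Myl9 had a log2 fold change of 0.77 and Sparc of 0.08 without passing. Tagln lost its call without knockout replicates 1 and 2 (adjusted p = 0.0731 and 0.0882) and Acta2 with each library left out (adjusted p 0.0567 to 0.327).

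Astrocyte and neuron lists gave weaker results. Of 22 tested astrocyte genes 0 were called over all genes (limma), 1 higher and 5 lower had an unadjusted p under 0.05, and 4 were lower adjusted over the list alone. The authors' deposited table calls 0 higher and 4 lower. The list was lower by camera at preset correlation (adjusted p = 0.0294), which was lost with an estimated correlation (adjusted p = 0.291), with a minimum of 5 FPKM (adjusted p = 0.461), under TPM scaling (adjusted p = 0.0515), after quantile normalization (adjusted p = 0.0656), without control replicate 1 (adjusted p = 0.106) and without knockout replicate 1 (adjusted p = 0.0764). Cldn10 and Cbs had log2 fold changes of -0.85 and -0.47, while the abundant Vim, Apoe, Gfap and S100b were at 0.05, 0.11, -0.14 and -0.11. Of 13 tested neuron genes 1 fell and 0 rose (limma), and 4 rose and 2 fell adjusted over the list alone. The list was higher by camera at preset correlation (adjusted p = 0.0214), which was lost with an estimated correlation (adjusted p = 0.291), without the filter on low values (adjusted p = 0.421), without control replicate 2 (adjusted p = 0.131), without knockout replicate 1 (adjusted p = 0.0610) and without knockout replicate 2 (adjusted p = 0.0648). The called member, Elavl3, an RNA-binding protein gene, went against the list and fell from 118.1 ± 1.31 to 82.5 ± 3.71 FPKM (SD, n = 2 each, log2 fold change -0.51, limma adjusted p = 0.0263; adjusted p 0.130 to 0.218 with each library left out), while Mapt, Ina, Map2 and Gap43 had log2 fold changes of 0.27, 0.35, 0.18 and 0.12.

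3 further lists passed at preset correlation. Of 11 tested interferon response genes 0 were called over all genes (limma), 4 higher and 0 lower had an unadjusted p under 0.05, and 4 were higher adjusted over the list alone, with 0 called in the authors' deposited table. The camera adjusted p was 0.00420, lost without knockout replicate 1 (adjusted p = 0.0764), and the adjusted p was 0.369 with an estimated correlation. The class I histocompatibility genes H2-K1 and H2-D1 had log2 fold changes of 0.42 and 0.35, B2m of 0.35 and Ifi27 of 0.57. Of 19 tested genes of the unfolded protein and integrated stress response, Slc7a11 rose over all genes (limma) and 2 rose adjusted over the list alone, with a camera adjusted p = 0.000402 and an adjusted p = 0.291 with an estimated correlation. The chaperone genes Calr, Hspa5 and Hsp90b1 had log2 fold changes of 0.24, 0.20 and 0.08, Xbp1 of 0.27 and Psat1 of -0.04. Of 49 tested ribosomal protein genes 0 were called (limma), 5 higher and 0 lower had an unadjusted p under 0.05, and 0 passed adjusted over the list alone, with 2 higher and 0 lower in the authors' deposited table. The camera adjusted p was 0.000377, lost without control replicate 2 (adjusted p = 0.250) and without knockout replicate 1 (adjusted p = 0.0680), and the adjusted p was 0.573 with an estimated correlation. Rps27 was at 4.09 and 10.3 FPKM in control and 60.3 and 21.5 in knockout, and its reads can be shared with its pseudogenes. Rpl38, Rplp1, Rps29, Rps28 and Rps19 had log2 fold changes of 0.06, 0.12, 0.10, 0.06 and 0.26.

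The remaining lists did not pass by camera. The camera adjusted p at preset correlation was 0.598 for 20 genes of BMP, Id and Notch signalling, among which Dll3 was called, 0.886 for 12 Wnt genes, 0.191 for 12 immediate early genes, 0.886 for 11 p53 and apoptosis genes, 0.729 for 18 hypoxia and glycolysis genes, 0.339 for 9 thyroid hormone signalling genes and 0.772 for 5 sex-linked genes. Adjusted over the list alone, 1 gene of the first list rose, 1 immediate early gene rose and 1 fell, and 0 passed in the other lists. The mean and median differ in sign for the Wnt list (-0.01 and 0.007) and the p53 list (0.005 and -0.02). In lists with fewer than 5 tested genes, 2 of 3 inflammatory genes were called, Vcam1 and Lcn2, with log2 fold changes of 0.69 and 0.70, named after their values were seen, and q = 0.162 for Lcn2 in the authors' deposited table, while 0 of 3 endothelial and 0 of 4 Schwann cell genes were called by limma. The calls of Vcam1 and Lcn2 were lost with each library left out (adjusted p 0.0986 to 0.236). Adjusted over the list alone, 3 inflammatory, 0 endothelial and 2 Schwann cell genes were higher. 0 of the 6 blood genes in the files reached the filter, and genes encoded by the mitochondrial genome were not analysed here. With an estimated correlation 0 of the 22 lists passed, and fry called 5, the newly formed, cholesterol, cell cycle, microglia and pericyte lists, and 4 of these without lncOL1, when the newly formed list did not pass (fry adjusted p = 0.0770 against 0.0478). The form with an estimated correlation had 2 residual degrees of freedom and so little power, and its 0 passes alone decide nothing about single lists. The estimated correlation was 0.354 for the ribosomal protein list, 0.145 for interferon and 0.09 for myelin, above the preset 0.01. Correlation between genes can thus account for the loss in the ribosomal protein list, and for part of it in the other 2. The ribosomal protein list also did not pass fry (adjusted p = 0.471). The mixed form of fry, which asks for changes in either direction and does not compare a list with other genes, passed for 17 of the 22, all but the PRC2 subunit, p53, thyroid hormone, ribosomal protein and sex-linked lists.

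The authors' deposited table calls 218 genes higher and 506 lower in the knockout at q under 0.05, among 12519 with a test. Among the 11154 genes with a test in both, 47 of the 57 genes higher by limma were also higher in the authors' deposited table, against 1 for independent lists of these sizes. For lower genes it was 83 of 89, against 3.9, and 0 genes were called in opposite directions. By list, it calls 1 higher and 12 lower among 34 myelin genes, and 2 higher and 10 lower among 20 newly formed oligodendrocyte genes. The higher and lower calls were 2 and 0 for microglia, 3 and 0 for pericyte, 3 and 2 for neuron and 3 and 1 for unfolded protein genes. Mbp had a log2 fold change of -0.93, H19 of 1.15 and Dll3 of 1.25 in the authors' deposited table. Tyrobp, at 1.23 there, did not pass (q = 0.134 in the authors' deposited table). The authors' pooled FPKM differ by over 1.5 times from the means here, in either group, for Dll3 (5.08 and 12.1 in control and knockout in the authors' deposited table), Tuba1c (282.9 and 318.0 there), Ppp1r3e, Atp6v0c-ps2, Ndufs5, Olig1, Olig2, Lhx2, Rps27, Tuba1b and Acat2, so the levels given for these genes are uncertain. Both sets of values come from the same libraries, so their overlap is not independent evidence.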

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

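The alternative without small RNA and pseudogene names was chosen after the data were seen, as was leaving lncOL1 out of the newly formed list; all others were fixed before. No called gene changed sign in any alternative. The counts of higher and lower genes, 60 and 89, became 105 and 135 with a pseudocount of 0.01, 1 and 3 with no filter on low values, 155 and 200 with robust moderation, and 154 and 186 without microRNA, snoRNA and pseudogene names and genes listed at 0. They became 158 and 183 with the replicate block. The replicate numbers are only shared names here, since no label ties them and the correlation of same-numbered deviations across genes was -0.052 (-0.105 over the 6056 genes with at least 10 FPKM). Leaving out 1 library gave 11 to 16 higher and 5 to 26 lower genes, with fewer samples and a lone sample assumed to vary like the others. The share of higher calls, 40.3% with all libraries, was 69.6% without knockout replicate 1 and 68.8% without knockout replicate 2. The other alternatives moved the counts by less than 1.5 times, and lncOL1 kept its call in all, at -2.56 to -2.25. The number of lists called, 11, became 0 with an estimated correlation and 5 with fry (4 without lncOL1 in the newly formed list), and 8 to 11 in the other alternatives. The 0 came from a form with 2 residual degrees of freedom, which few lists could pass. For some lists it also used a correlation above the preset 0.01, such as 0.354 for the ribosomal protein list. With a minimum of 5 FPKM the microglia, pericyte, PRC2 target and sex-linked lists had too few genes for a test. The authors' table, at 218 higher and 506 lower, gave 139 higher at q under 0.01 and 38 higher and 23 lower with at least a 2-fold change. Of 45 called genes named beside lncOL1, 44 lost the call with no filter on low values, and 7 of 441 gene and setting pairs with all libraries and a filter did. The sign changes below were in genes not called by limma and lists not called by camera or by fry for 1 direction. Their cause was not tested. For the PRC2 targets, TPM scaling also lowered the filter, and Six3 and Nkx2-1 entered the tested members. The mixed form of fry, for changes in either direction, did pass for the lineage transcription factor, PRC2 target, BMP, Id and Notch, and Wnt lists (adjusted p = 0.0266, 0.0266, 0.0159 and 0.0131). After quantile normalization the log2 fold change was 0 for Sirt2, -0.017 for Fyn, -0.023 for Sox10 and 0.001 for Rbbp4. With 1 library left out it ranged from -0.032 to 0.144 for Bcas1, -0.006 to 0.116 for Fyn, -0.035 to 0.202 for Olig1, -0.071 to 0.116 for Sox10, -0.084 to 0.078 for Bcan, -0.082 to 0.037 for Nnat, -0.022 to 0.166 for Scrg1 and -0.276 to 0.074 for Aebp2. It ranged from -0.141 to 0.069 for Eed, -0.074 to 0.147 for Mtf2, -0.064 to 0.142 for Phf1, -0.03 to 0.017 for Rbbp4, -0.053 to 0.026 for Rbbp7, -0.038 to 0.16 for Suz12 and -0.01 to 0.112 for Vim. For the others it was -0.012 to 0.225 for Apoe, -0.109 to 0.344 for Gap43, -0.088 to 0.256 for Hsp90b1, -0.113 to 0.232 for Rpl38 and -0.032 to 0.057 for Pcdh17. The list means that turned, or whose test did, were 0.009 for the lineage transcription factors and -0.004 for the Wnt list with a minimum of 5 FPKM, 0.106 for PRC2 targets under TPM scaling, -0.014 for the Wnt list by fry, and 0.013 for the p53 list both with no filter and with a minimum of 5 FPKM. With 1 library left out list means ranged from -0.027 to -0.008 for the lineage transcription factors, -0.059 to 0.027 for PRC2 subunits, 0.049 to 0.105 for the BMP, Id and Notch list, -0.031 to 0.003 for the Wnt list, -0.03 to 0.04 for the p53 list and -0.055 to 0.081 for the sex-linked list. Read counts are not given in the files, so what depth limits was not measured.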

Other observations

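Of the tests below, those on lineage cells, dividing precursors, imprinted genes, fibroblasts and contractile cells, and the share of all genes below the filter that rose, were chosen after the result was seen, and the test on microglia genes below the filter was added after the data were seen but before its own result. The called genes outside the fixed lists given here were chosen after their values were seen, with no enrichment test. Sema6a, Sema6d, Slit2 and Efnb3, which encode guidance cues, were picked by hand among the lower genes, and other guidance genes were not counted. Sema6a went from 131.5 to 91.0 FPKM (log2 fold change -0.53), Sema6d from 63.7 to 43.4 (-0.54), Slit2 from 7.06 to 4.03 (-0.68) and Efnb3 from 15.8 to 8.33 (-0.85), with limma adjusted p-values of 0.0269, 0.0182, 0.0128 and 0.00539. Fgfr2, a growth factor receptor, and Tppp, a microtubule-binding protein of oligodendrocytes, also fell, by 0.85 and 0.96 on the log2 scale (limma adjusted p = 0.00579 and 0.00433). With each library left out in turn the calls of Sema6a, Sema6d, Slit2 and Fgfr2 were lost (adjusted p 0.0626 to 0.238), that of Efnb3 held only without control replicate 2 (adjusted p = 0.0478), and that of Tppp was lost without knockout replicate 2 (adjusted p = 0.0700).

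Among the higher genes, Cnn2, another gene of the contractile cytoskeleton, went from 5.56 to 11.1 FPKM (log2 fold change 0.88, limma adjusted p = 0.00514). The authors' deposited table gives q = 0.806 for Cnn2. The calcium-binding protein genes S100a13 and S100a16 rose by 0.92 and 0.75 on the log2 scale, and Acat2, an enzyme of sterol precursor supply, by 0.44. Tuba1b rose by 0.64, with reads that can be shared with other tubulin genes. The imprinted genes Igf2, Meg3 and Ipw rose beside H19, by 0.90, 0.67 and 0.74 (limma adjusted p = 0.00504, 0.0113 and 0.0191). The calls of Cnn2, S100a16, Acat2, Tuba1b, Meg3 and Ipw were lost with each library left out (adjusted p 0.0564 to 0.244), that of S100a13 without knockout replicates 1 and 2 (adjusted p = 0.0726 and 0.0866), and that of Igf2 held only without control replicate 1 (adjusted p = 0.0396).

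Splitting the 4 libraries into pairs the other ways gave at most 6 called genes against 149 for the real split, and 1 of 3 splits, the real one, reached that number; 3 splits are too few for a share under 0.05.

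The myelin list was lower by camera at preset correlation, but not with an estimated correlation (adjusted p = 0.291) or by fry (adjusted p = 0.0664), and 5 of 35 members fell, at -0.50 or below, while 10 were positive. The tables argue against a smaller share of oligodendrocyte-lineage cells as the whole cause, since Olig1, Olig2, Sox10 and Sox8 had a median log2 fold change of 0.14 and none was below 0.02 with all libraries, although Sox10 was at -0.023 after quantile normalization, and Olig1 and Sox10 reached -0.035 and -0.071 with 1 library left out and were at -0.037 and -0.092 in the authors' deposited table, where the levels of Olig1 and Olig2 also differ by over 1.5 times. A smaller share would also raise other cell types alike, and the microglia median lay 0.67 above the astrocyte median (permutation p = 4e-05, over genes that are not independent). That contrast does not decide, since it rests on the astrocyte list, with a median of -0.021. The other medians were positive, at 0.65 for microglia, 0.603 for pericyte and 0.178 for neuron genes. Those of the endothelial and Schwann cell lists, with fewer than 5 genes tested, were 0.192 and 0.241. More dividing precursors are argued against by cell cycle genes with a mean of -0.243 (95% bootstrap interval -0.301 to -0.185, over genes that are not independent), a list lower by fry (adjusted p = 0.0471) but not by camera with an estimated correlation (adjusted p = 0.225). A slower maturation on loss of lncOL1, and the genotype mix of the controls and the mixed strain background, stay open and were not tested. The level of Olig1, Olig2, Sox10 and Sox8 per cell was not measured, so a smaller share beside slower maturation also stays open.

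The microglia list was higher by camera at preset correlation, with 2 of 10 tested members called, but not with an estimated correlation (adjusted p = 0.231), and more microglia or macrophages in those cultures is a candidate explanation. It predicts that the list members too low to be tested rise as well, and 13 of 15 were higher in the knockout (two-sided exact sign test p = 0.00739, or exact binomial p = 0.0182 against the 56.1% of all 6036 genes above 0 and below the filter that were higher, over genes that are not independent). Below the filter, 14 of 14 inflammatory, 10 of 13 endothelial and 5 of 6 blood genes were higher too, against 7 of 14 neuron and 8 of 18 pericyte genes. These counts cannot say whether the rise was special to microglia. The inflammatory genes were not assigned to a cell type here. Many of the values were near 0, such as endothelial Cdh5 at means of 0.03205 FPKM in control and 0.03206 in knockout. The levels were low, with Lyz2 at 6.64 and 8.28 and Tyrobp at 1.66 and 4.32 FPKM in control and knockout. Of the 25 list members, 10 reached a mean of 1 FPKM over the 4 libraries. Whether such cells differed because of the genotype or between preparations was not tested.

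For H19 and Igf2, both higher in the knockout, the tables argue against a joint rise of imprinted genes by about the change of H19, because the median over 22 imprinted genes tested, these included, was 0.062 (95% bootstrap interval 0.014 to 0.234, against 0.613, the change of H19 divided by 2). The test was revised, from a version without H19, Igf2, Meg3 and Ipw (median 0.044 over 18 genes, camera adjusted p = 0.107 over the 3 versions) to one with H19 (0.058 over 19, adjusted p = 0.0329 at preset and 0.196 with an estimated correlation) and then to all 22, of which 4 were called higher and 16 had a positive log2 fold change (adjusted p = 0.000297 at preset and 0.151 with an estimated correlation). More fibroblasts or meningeal cells are argued against because Col1a1, Col1a2 and Col3a1 together changed by -0.604 FPKM while H19 rose by 325.8. These collagen genes had means under 1 FPKM in both groups. All 7 tested members of the pericyte, fibroblast and meningeal list, matrix genes among them, had a positive log2 fold change, so this argument is limited. All 26 pericyte, fibroblast and meningeal list genes together rose by 16.5 (from 79.86 ± 2.426 to 96.31 ± 1.645, SD, n = 2 each), with Tagln up by 7.4 and Acta2 by 1.8. This does not decide on more cells of a contractile type as the source of H19, since their H19 level is not known. More such cells would raise by a like factor only those genes whose RNA comes wholly from them, which is not known for H19, Igf2 or Sparc. Of the 18 list members above 0 and below the filter, 8 were higher in the knockout. Knockout over control FPKM was 2.03 for Tagln, 2.23 for Acta2, 1.86 for Myl9 and 1.06 for Sparc, against 2.34 for H19 and 1.95 for Igf2. Contractile cells stay open for H19 and for Igf2, which rose by 9.2. A smaller common shift of imprinted genes and strain differences in the mixed background also stay open for both.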
